A study of Bos taurus with 14 samples.

How the data were processed

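Paired-end mRNA libraries were made from total RNA of frozen milk of 14 cows, per the labels' protocols, and each cow is 1 sample. Genotype and sample number were taken from the sample titles, giving 7 A1A1 and 7 A2A2 cows. The labels state no pairing, and each sample number occurs once, which can neither show nor exclude one. The cows were treated as unpaired. The descriptions of 4 samples (A1A1 10 and 15, A2A2 5 and 13) end in _2, which the labels do not explain, and this suffix was treated as a possible batch.

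The authors deposited raw counts per gene and FPKM for the same 36075 Ensembl cattle identifiers. The submitters' processing notes name FastQC 0.11.9, cutadapt 4.0, STAR and edgeR 4.0.16 without saying what each was used for. The genome build, the annotation and the counting tool are not given in the sources used here. In the deposited FPKM values, counts divided by FPKM gave the same gene length in every library up to 1 factor per library, and these factors lie within 3.02% of TMM factors computed here. The implied length of all 21104 genes with a count lies within 0.05 of a whole number of bases.

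The reference table of the assembly ARS-UCD2.0 matched 0 of the 36075 identifiers to a gene symbol, since its column of Ensembl identifiers is empty. Tests fixed by name before the data were examined were therefore not run. These are the camera test of 32 gene lists, that of mitochondrial-encoded protein genes included, the genes near CSN2, and the 6 main milk protein genes. The ratio of CSN2 to the other caseins was not run either, nor were the measures of milk protein, mitochondrial-encoded, ribosomal and cell type genes. The planned rule for named genes needs symbols in its first 4 parts. Its last part, the 10 genes of highest abundance, was kept, and in place of the rest the 2 lower and the 2 higher genes of smallest p with at least 10 counts in at least 5 libraries of the higher group are given by identifier.

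The mitochondrial-length genes were defined by length after the gene tests had been seen. For each of the 15 protein and rRNA genes of the mitochondrial genome in the reference table, the most abundant gene of exactly that length was taken from the 50 genes with the most counts, which gave 12 genes. The 5 genes that vary together are those among the 50 whose log2 CPM has a Pearson correlation of at least 0.95 with the gene of rank 10. The 8 other abundant genes are those of ranks 2 to 11 outside these 2 sets. The sets of 5 and 8 genes were formed after the data were seen.

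Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, robust quasi-likelihood F test, A2A2 minus A1A1, two-sided) on 12320 genes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values use TMM factors, and differences in mean log2 CPM use a pseudocount of 0.5. Shares of counts, principal component scores and abundant genes were compared by exact permutation tests over all 3432 splits of 14 libraries into 7 and 7, two-sided. Gene groups were tested with camera and fry in limma 3.58.1. Single shares carry exact binomial 95% intervals, and a count of 0 allows up to 3 counts of a library's total.

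The scripts were tested on counts simulated from the library sizes and from each gene's own mean and spread, with genes drawn independently. Among 12320 genes, 50 each were changed 2-, 4-, 8- and 16-fold. edgeR recovered 22, 70, 88 and 96% of them and called 3 unchanged genes. DESeq2 1.42.0 recovered 42, 90, 100 and 100% but called 37 unchanged genes, and 11 in a simulation with no change, where edgeR called 0.

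The alternatives tried were RLE factors, library totals, no filter, a CPM of at least 1 in 7 libraries, each library left out in turn, the suffix as a covariate, the 10 libraries without it, 1 surrogate variable (sva 3.50.0), DESeq2, limma voom with quality weights, edgeR without robust estimation, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 7 libraries and without that filter. TMM without the 50 most abundant genes, the fit without A1A1 3, 7 and 9, and all alternatives for the mitochondrial-length genes, the 5 genes that vary together and the 8 other abundant genes were chosen after seeing the data. The real grouping was set among splits of the libraries drawn at random, 100 in all for edgeR and 25 in all for DESeq2, with the real one counted in both.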

Results

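RNA carried by milk fat globules was profiled in 14 purebred Holstein cows of 1 commercial farm. Milk fat globules are the droplets in which the secretory cell of the udder releases fat, and they enclose some of that cell's cytoplasm and its RNA. The cows were kept under the same management and fed the same rations. 7 were homozygous for the A1 form and 7 for the A2 form of β-casein, a major milk protein, and each cow gave 1 library. The comparison asked how the globule transcriptome differs between the A1A1 and A2A2 genotypes. Total counts per library ran from 16116849 in A1A1 7 to 22994197 in A2A2 11. Their means were 19301129 ± 2053233 in A1A1 and 21104426 ± 1764769 in A2A2 (SD, n = 7 each, exact permutation p = 0.103, two-sided; 0.0221 without A2A2 17, 0.0495 without A1A1 2 and 0.473 without A1A1 3, 7 and 9). Of 36075 gene identifiers, 21104 had at least 1 count and 12320 were tested, and the tested genes held 99.9% of all counts. The files and the reference table do not pair the identifiers with gene names, so genes are described by their abundance rank (rank 1 has the most counts over all libraries), by their length in bases or, for 4 genes, by identifier.

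A group of 12 abundant genes was lower in A2A2 than in A1A1 milk fat globules, by a median log2 fold change of -1.29. Each of the 12 has the length of a protein or rRNA gene of the mitochondrial genome in the reference table, and they are called the mitochondrial-length genes below. They took 26.7 ± 12.8% of the counts of a library in A1A1 and 12.1 ± 5.20% in A2A2 (SD, n = 7 each), a difference of -14.5 percentage points (exact permutation p = 0.00641, two-sided). On the log2 scale the share differed by -1.13, with a 95% interval of -1.88 to -0.36 from the exact permutation test. A share of mitochondrial-encoded genes chosen by name had been planned but could not be run. This group, by contrast, was noticed and defined by length after the gene tests had been seen. Adjusted over 9 library measures the p was 0.0577, which does not pass 0.05 (Benjamini-Hochberg on exact permutation p). Over a family of the size planned, 16 measures, most of which need gene names, it could be as high as 0.103.

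**Figure D1:**
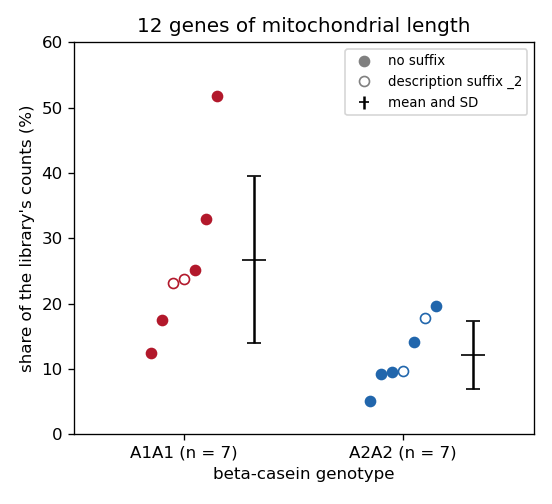
Share of each library's counts (%) taken by the 12 mitochondrial-length genes, by β-casein genotype. Each point is 1 cow, open points are libraries with the description suffix _2, and bars give the mean and SD; 4 A2A2 libraries lie below every A1A1 library.

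All 12 mitochondrial-length genes were lower in A2A2, with log2 fold changes between -1.56 and -1.04. The gene of rank 1, 1545 bases long, had a CPM of 103816 ± 54301 in A1A1 and 39016 ± 16356 in A2A2. The gene of rank 7 had 42092 ± 17922 and 18136 ± 6710. The gene of rank 22 had 10605 ± 3445 and 4095 ± 1683, and that of rank 19 had 10022 ± 3916 and 4877 ± 1937 (SD, n = 7 each throughout). In edgeR's quasi-likelihood test 0 of the 12 passed an adjusted p of 0.05 over all genes tested, and 12 of 12 passed when adjusted over the list alone, with adjusted p between 0.00319 and 0.00725. The second count is not independent evidence, since the group was formed after the gene tests. Set against all other genes by camera in limma, the group had p = 0.00189 with the estimated correlation of 0.827. A preset correlation of 0.01 gave p = 1.06e-32, which is not valid here because the estimated correlation is far higher. fry, which tests whether the genes move one way on balance, gave p = 0.00219. The camera and fry p-values are not independent evidence either, since both tested the group formed after the gene tests. The share ran from 5.12% in A2A2 17 (exact binomial 95% interval 5.11 to 5.13%) to 51.8% in A1A1 9 (51.8 to 51.8%). These intervals cover counting error only. Among the 10 libraries whose description lacks the suffix _2, the share was 28.0% in A1A1 and 11.5% in A2A2, a difference of -16.5 points (exact permutation p = 0.0397). In the 4 libraries with the suffix it was 23.4% and 13.7%, a difference of -9.72 points between 2 cows and 2 cows, for which no test was run.

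**Figure D2:**
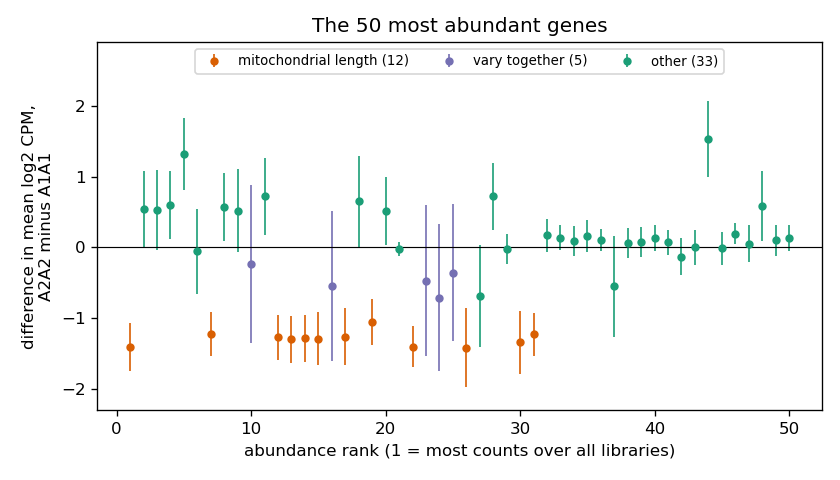
Difference in mean log2 CPM (A2A2 minus A1A1, bars 1 standard error) of the 50 most abundant genes against their abundance rank. The 12 mitochondrial-length genes lie below 0, and the genes of ranks 5 and 44 lie above 1.

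Of the other genes among the 10 most abundant, only that of rank 5 differed between the genotypes within this family of 10, and it did not pass over all genes. This gene, which is 1192 bases long, had a CPM of 21540 ± 10674 in A1A1 and 47124 ± 16430 in A2A2 (SD, n = 7 each). Its log2 fold change was 1.13. Leaving out 1 library gave 0.94 to 1.27, lowest without A1A1 9, and 1 surrogate variable gave 0.80. Over the 10 most abundant genes it had an exact permutation p of 0.00758, adjusted p = 0.0253, against an adjusted p over all genes of 0.856 in edgeR, 0.991 in DESeq2 and 0.481 in limma voom. In the same family of 10, tested this way after the data were seen, the genes of ranks 1 and 7 each had an adjusted p of 0.00583 by the exact permutation test. The gene of rank 44, singled out after its values were seen, is 591 bases long and had 843 ± 420 CPM in A1A1 and 2241 ± 1112 in A2A2. Its log2 fold change was 1.41, and it did not pass in edgeR (adjusted p = 0.856). The genes of ranks 2, 3, 4, 8 and 9 had log2 fold changes of 0.22, 0.19, 0.38, 0.30 and 0.19, and those of ranks 6 and 10 had -0.48 and -1.08. For these 7 genes the adjusted p over the 10 most abundant genes was 0.558 or more (exact permutation tests), so no genotype difference was detected for them. The sizes of all 7 varied with single libraries, and the directions changed for ranks 3, 9 and 10 only. Leaving out 1 library gave 0.017 to 0.34 for rank 2, -0.010 to 0.34 for rank 3, 0.19 to 0.61 for rank 4, 0.11 to 0.54 for rank 8 and -0.014 to 0.37 for rank 9, each lowest without A1A1 9. It gave -0.70 to -0.048 for rank 6 and -1.90 to 0.38 for rank 10, both highest without A1A1 3. Outside the mitochondrial-length group, 2 of the 38 other genes among the 50 most abundant had an unadjusted edgeR p under 0.05. That is 5.26%, where chance gives 5%.

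Across all tested genes, edgeR called 0 genes different between the genotypes, with a smallest adjusted p of 0.738. 411 genes had an unadjusted p under 0.05, 265 of them lower and 146 higher in A2A2. 5% of the genes tested is 616, and counts simulated with no change gave 551. Leaving out 1 library gave 224 to 1364 genes. The balance of directions depended on the setting, with more genes higher than lower when library totals replaced TMM (547 and 80), in the 10 libraries without the suffix (176 and 117), with 1 surrogate variable (89 and 83), without A1A1 15 (287 and 225) and by limma on log2(FPKM + 1) (180 and 154) or log2(FPKM + 0.1) (172 and 134). The TMM factors were 0.946 ± 0.152 in A1A1 and 1.07 ± 0.0752 in A2A2 (SD, n = 7 each, exact permutation p = 0.0490, adjusted p = 0.196 over 9 library measures). limma voom with quality weights also called 0 genes, and DESeq2 called 5, of which 4 were lower and 1 higher in A2A2. 3 of these 5 are given by identifier in the next paragraph, and the other 2, both lower in A2A2, are 67 and 1571 bases long. The gene of 1571 bases is that of rank 22, 1 of the 12 mitochondrial-length genes. The gene of 67 bases and ENSBTAG00000043546, which is 528 bases long, also have lengths of mitochondrial genes, so this holds for 3 of the 5. 5 tested genes had no overlap between the genotypes, 4 lower and 1 higher in A2A2, where chance gives 7.18 genes or 0.0583%. The biological coefficient of variation was 51.8%. In counts simulated with each gene's own spread, edgeR recovered 22% of genes changed 2-fold, 70% of those changed 4-fold and 88% of those changed 8-fold. Most 2-fold changes thus went undetected there. Genes were drawn independently and many changed at once, so these rates are not those of a single changed gene in these libraries.

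The 2 genes of smallest p in each direction did not pass in edgeR. ENSBTAG00000043546 had a CPM of 71.4 ± 26.4 in A1A1 and 26.7 ± 11.1 in A2A2, and it was below every A1A1 library in 6 of 7 A2A2 libraries. Its difference in mean log2 CPM was -1.41 with a standard error of 0.289, and its adjusted p was 0.738. ENSBTAG00000016711 had 10.3 ± 1.14 and 5.67 ± 1.22 CPM, without overlap between the genotypes (difference -0.83, standard error 0.122, edgeR adjusted p = 0.738). ENSBTAG00000051698 had 0.178 ± 0.185 and 4.01 ± 2.71 CPM, with 0 to 11 counts in A1A1 libraries and 1 to 169 in A2A2 libraries (difference in mean log2 CPM 2.32, standard error 0.587, edgeR adjusted p = 0.738). The size depends on the scale, since the log2 fold change fitted by edgeR was 4.40 and the lowest of 25 alternatives was 1.54, by limma on log2(FPKM + 1) without a filter. ENSBTAG00000000828 had 0.797 ± 0.776 and 12.1 ± 13.04 CPM (difference 2.79, standard error 0.716, edgeR adjusted p = 0.856). Its fitted log2 fold change was 3.87, and it was 3.25 without A2A2 1, which had 37.9 CPM, and 1.71 by the same limma fit.

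The first principal component held 46.1% of the variance and ran from -123 in A1A1 7 to 122 in A1A1 9. No genotype difference was detected on it (exact permutation p = 0.241). The second held 10.9% and parted the 4 libraries with the suffix _2 from the other 10, with means of 38.3 and -15.3 (exact permutation p = 0.000999, the smallest these splits can give, adjusted p = 0.00899 over 9 measures). Between these libraries edgeR called 111 of 13323 genes at an adjusted p of 0.05, with 55 higher and 56 lower with the suffix, whose meaning is not stated in the labels. Each genotype has 2 libraries with the suffix.

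**Figure D3:**
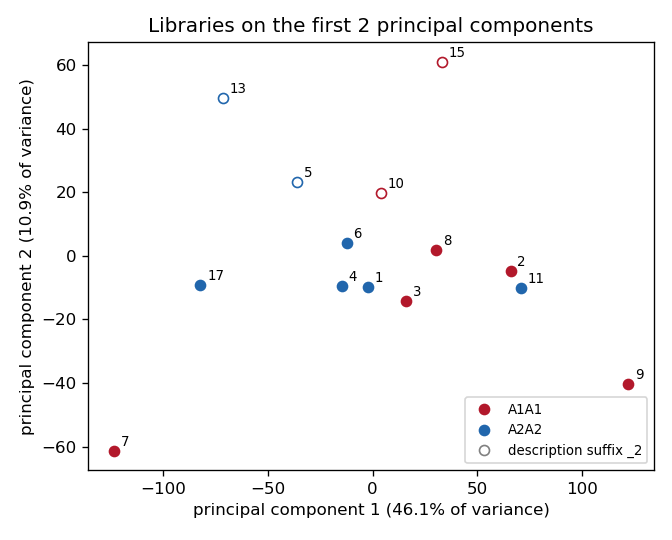
Libraries on the first 2 principal components of log2 CPM, labelled by sample number and coloured by genotype, with open points for the description suffix _2. The 4 open points lie highest on the second component, and A1A1 7 and A1A1 9 lie at the ends of the first.

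A set of 5 abundant genes, of ranks 10, 16, 23, 24 and 25, varied together between cows. They took 0.466% of the counts in A1A1 10 and 23.7% in A1A1 3, a 50.8-fold range, and their share differed between the genotypes by less than the spread between cows (5.59 ± 8.37% in A1A1 and 3.65 ± 4.38% in A2A2, SD, n = 7 each, exact permutation p = 0.671). The difference of -1.95 points was 1.07 without A1A1 3 and -3.44 without A2A2 6. The 8 genes of ranks 2 to 6, 8, 9 and 11 took 26.7 ± 12.2% of the counts in A1A1 and 37.4 ± 7.70% in A2A2 (SD, n = 7 each, exact permutation p = 0.0653). The difference of 10.7 points was 6.81 without A1A1 9 (exact permutation p = 0.132) and 2.83 between medians (p = 0.604), and leaving out 1 library gave p between 0.0344 and 0.138. Both sets were formed after the data were seen, and over 9 library measures the adjusted p was 0.732 for the 5 genes and 0.196 for the 8 (Benjamini-Hochberg on exact permutation p). In A1A1 9 the 8 genes took 3.59%, and the lowest share among the other 13 libraries was 21.5%.

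**Figure D4:**
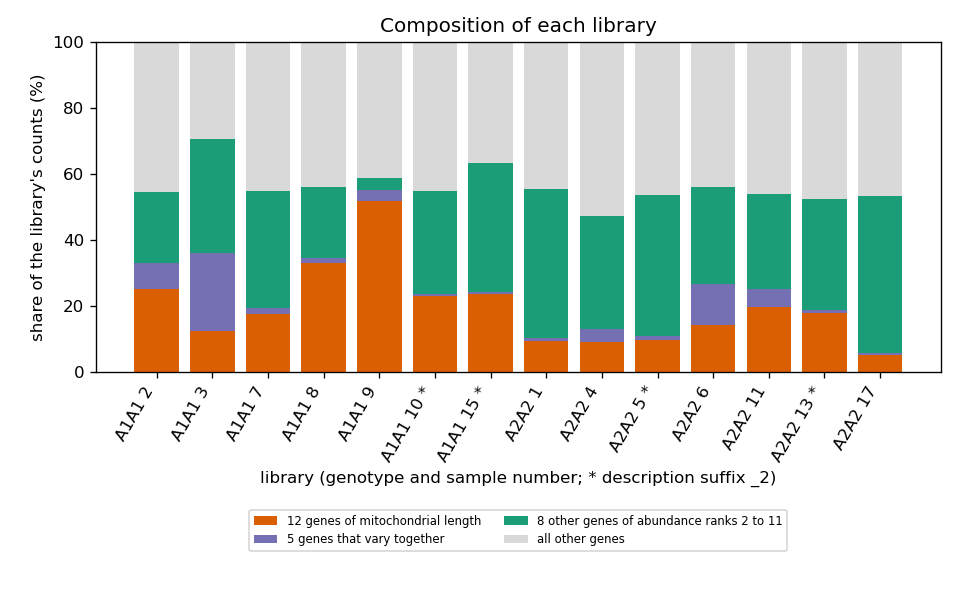
Share of the counts (%) of each library taken by the 12 mitochondrial-length genes, the 5 genes that vary together, the 8 other genes of ranks 2 to 11, and all other genes. The mitochondrial-length genes take 51.8% in A1A1 9 and 5.12% in A2A2 17.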

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

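Within each genotype, 44 sets of 7 values were searched for a library far from the other 6 (Dixon's test), and 10 were found. For normally distributed values chance gives about 1 in 20 sets. CPM and shares of counts were searched without a log scale and can be skewed, in which case chance gives more. The sets overlap, since several measures share genes. The test without A1A1 9 below was chosen after the result was seen.

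A1A1 9 had a CPM of 222371 for the gene of rank 1, against 66645 to 108445 in the other A1A1 libraries, and 79041 for the gene of rank 7, against 26178 to 47578. Both are mitochondrial-length genes. If this cow alone made the genotype difference, the difference would shrink to under 50% without it. Without A1A1 9 the share of these genes still differed by -10.3 points (exact permutation p = 0.0117), which is 71.2% of the difference with all libraries. One extreme library therefore accounts for part of the difference in size but not for its direction.

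A1A1 3 had a TMM factor of 0.636, against 0.908 to 1.10 in the other A1A1 libraries. The 5 genes that vary together took 23.7% of its counts, against at most 7.821%, and its gene of rank 10, one of the 5, had 155901 CPM, against at most 35405. In A2A2 6 the same 5 genes took 12.6%, against at most 5.51% in the other A2A2 libraries, and the gene of rank 10 had 54984 CPM, against at most 22585.

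A2A2 17 had a total count of 17499819, below the other A2A2 libraries, which had at least 20965736. A2A2 1 had 37.9 CPM of ENSBTAG00000000828, against at most 16.9 in the other A2A2 libraries, and 111654 CPM of the gene of rank 2, against at most 78380.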

How the results depend on the processing

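The count of 0 called genes was the same in 27 of 29 alternatives, including all 14 fits that leave out 1 library (lowest 0, highest 0). DESeq2 called 5 genes (1 higher, 4 lower), and limma on log2(FPKM + 1) called 1 gene, which was lower. That gene has the length of a mitochondrial gene but is not among the mitochondrial-length genes of this text. The cause of these calls was not tested. The number at an unadjusted p under 0.05 depended more on the setting. It was 411 in the main test, 1881 without a filter, 1276 by voom, 646 with the suffix as a covariate, 172 with 1 surrogate variable and 741 without A1A1 3, 7 and 9. It was 262 without A1A1 2, 1364 without A1A1 7, 267 without A1A1 9, 1355 without A2A2 11, 269 without A2A2 13 and 224 without A2A2 17. With library totals in place of TMM, the median log2 fold change of all genes moved to 0.18.

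The mitochondrial-length genes were lower in A2A2 under every alternative run, DESeq2 included, where camera was not run, with a median log2 fold change between -1.49 and -0.90 and a camera p of 0.0103 or less with an estimated correlation. Leaving out 1 library gave -1.49 to -1.03. The difference in their share of counts lay between -18.8 and -10.3 points, with an exact permutation p of 0.0397 or less. These alternatives were chosen after seeing the data.

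Directions changed for the genes of ranks 3, 6, 9 and 10 and for 3 measures of the libraries. With 1 surrogate variable the log2 fold change was -0.15 for rank 3 and -0.050 for rank 9. By voom it was 0.13 for rank 6 and 0.24 for rank 10, and without A1A1 3, 7 and 9 it was 0.47 for rank 10. Leaving out 1 library gave -0.010 to 0.34 for rank 3 and -0.014 to 0.37 for rank 9, both lowest without A1A1 9, and -1.90 to 0.38 for rank 10, highest without A1A1 3. The difference in genes detected was -228 in the main test, 170 without the suffix libraries and -1033 without A1A1 3, 7 and 9 (exact permutation p = 0.0424); leaving out 1 library gave -688 to 62. The difference in the share of the 10 most abundant genes was 1.62 points between means and -0.84 between medians. Leaving out 1 library gave 0.061 without A1A1 9 to 3.02 without A1A1 15 for this share. For the 5 genes that vary together the difference in share was -1.95 points, and 1.10 without A1A1 3, 7 and 9. It was -3.44 to 1.07 when leaving out 1 library, highest without A1A1 3. TMM without the 6 milk protein genes, the leucocyte covariate and all alternatives of the tests that need gene names were not run.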

Other observations

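The tests of chance for the mitochondrial-length genes and of their identity by the remaining mitochondrial lengths were chosen after the results were seen.

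Chance cannot be excluded for the gene counts. 42 of 100 splits of the 14 libraries, the real one included, gave at least the 411 genes that edgeR found at an unadjusted p under 0.05, and the other splits had a median of 311 and a highest of 2874. 5 of 25 splits, again with the real one, gave at least the 5 genes that DESeq2 called, and the highest other split gave 159. Splits far above the real number could reflect a structure of the libraries other than genotype, which was not tested. In 1 simulation without any change, each of 12320 genes was drawn on its own. DESeq2 called 11 genes there, and edgeR gave 551 at an unadjusted p under 0.05. The highest other splits lie above both numbers, which such a simulation does not account for. The DESeq2 splits covered the 21104 genes with a count, so its numbers are not for the same genes.

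The lower level of the mitochondrial-length genes in A2A2 was larger than in any other split drawn. The real split was the only 1 of 100 to reach a median log2 fold change of 1.29 in size, and the highest other split gave 1.17. The genes of the group were picked by length and by counts over all libraries, without regard to genotype, so each split would give the same genes. The decision to look at them, however, came after the gene tests of the real split had been seen. The other splits had no such choice, so this result does not exclude chance. Against the genes outside the 50 most abundant, their log2 ratio differed by -1.32 (exact permutation p = 0.00117), so other abundant genes taking more of the counts in A2A2 do not account for it. With the first principal component of the other genes as a covariate the difference was -1.06 (permutation p = 0.00237). This argues against the main axis between cows as the whole cause. The suffix _2 falls on 2 libraries of each genotype, and the share was 18.6% with it and 19.7% without it (exact permutation p = 0.881). The design thus already speaks against the suffix, and the difference of -16.5 points among the 10 libraries without it adds little. A difference tied to genotype stays open as a hypothesis, as do chance, stage of lactation, parity, udder health and RNA quality, the last 4 of which the labels do not give and which could differ between 7 cows and 7 cows.

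A candidate explanation for the 12 lengths is that these genes are mitochondrial transcripts. Shifting the 15 lengths by 1 to 100 bases either way matched at most 3 of the 50 most abundant genes, against 12 unshifted, which argues against a coincidence of lengths. As a further test, the most abundant gene of each of the 13 other mitochondrial gene lengths was taken. 8 of these passed the count filter, and 7 of the 8 were lower in A2A2 with an unadjusted p under 0.05. Their median log2 fold change was -1.68, and 0 of 10000 random sets of tested genes were as low. The random sets were drawn gene by gene, without regard to genes that vary together, so this number does not measure chance. Some of the 8 genes had also already been seen among the DESeq2 calls and the smallest edgeR p-values.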
